A study of Gadus morhua with 8 samples.

How the data were processed

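Gill RNA of Atlantic cod (Gadus morhua) was measured on oligonucleotide microarrays in 5 samples labelled Gdansk Bay and 3 samples labelled Kiel Bight. Per the labels, total RNA was extracted from gill and each sample's RNA was labelled with Cy5 by Agilent's two-color protocol. A mix of all samples, labelled with Cy3, served as the common reference on every array, so no dye was swapped and the reference cancels in a difference between regions. The design text gives a salinity of 8 PSU (practical salinity units) for Gdansk Bay and 18 PSU for Kiel Bight.

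The deposited values are normalized log2 ratios, Cy5 over Cy3 and thus sample over reference, per the file headers. Agilent Feature Extraction 10.10.1.1 and limma (version not given) were used, per the submitters' processing notes. The background correction, the within-array and between-array normalization, and any filter are not given in the sources used here. The table listed 43892 of the spot numbers up to 45220, and 42475 spots had a value on all 8 arrays. The other 1417 listed spots were blank on all arrays, and 1328 spot numbers were not listed in the table used here. The deposited log2 values carried no channel intensities, so background and saturation could not be examined. The number of arrays limits the precision, and how far background limits low ratios, and the folds that rest on them, is unknown.

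The table identifies spots by number alone and does not pair them with genes or probe sequences. Spots are therefore reported by number, repeated spots of a probe could not be averaged, and spots of the same gene are not independent. Gene-level tests and tests of gene lists for ion transport, cell junctions, osmolytes, stress, immunity, metabolism and markers of other gill cell types had been planned before the data were examined, but need gene names and were not run. The rule for naming, also fixed before the data were examined, allowed at most 2 spots in each direction where no gene names were at hand. They were taken by the order planned for genes, the largest difference among called spots with no overlap between the regions. The 2 other called spots are given without their numbers.

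Each array column was matched to its sample by region code and number. A linear model with region as the only factor was fitted to the deposited log2 ratios of all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and the contrast was Gdansk Bay minus Kiel Bight. Spots with a Benjamini-Hochberg adjusted p under 0.05 over all 42475 spots were called. The model was tested on simulated data made from each spot's own spread within regions, with 50 spots changed at each of 4 sizes. It called 58% of spots changed by 0.5 log2, 74% of those changed by 1 log2, 92% of those changed by 2 log2 and 100% of those changed by 3 log2. Of the unchanged simulated spots, 10 were called. The simulated spots varied independently, and all 4 sizes were planted at once. Far more spots were thus called than in the data, which eases the adjusted threshold. These shares can therefore overstate what the real comparison could find.

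Whether arrays of a region resembled each other was measured as the mean between-region minus the mean within-region distance (1 minus Pearson's r over all spots). It was tested exactly over all 56 splits of the 8 arrays into 5 and 3, one-sided. Spots with a gap of at least 2 log2 (4-fold) between neighbouring samples in rank order were also listed. This gap was chosen after the data had been examined with gaps of 1.5, 2 and 3 log2. The samples above the widest gap of such a spot are called high and those below it low.

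Alternatives were median centring, quantile normalization and scaling of the arrays, a variance filter, robust and unmoderated tests, array weights, a minimum difference, another threshold, the replicate number as a block, other distances, and leaving out each array. A covariate for the first within-region component, a fit of numbers 1 to 3 without the block and other gap sizes were added after the data were examined. The labels number the samples but do not say that each is a separate fish, so p-values measure the spread between these samples.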

Results

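Log2 ratios against a pooled gill reference were available for 42475 spots in 8 gill samples, 5 from Gdansk Bay (8 PSU) and 3 from Kiel Bight (18 PSU). The median log2 ratio of an array lay between 0.0056 and 0.0152, and the standard deviation over spots lay between 0.257 and 0.295. Between 59 and 103 spots per array differed from the reference by more than 2 log2. Most spots varied little, with a median range over the 8 samples of 0.301 log2. A range of at least 1 log2 was seen at 4819 spots (11.4%), and a range of at least 2 log2 at 939 spots (2.21%). The median standard deviation of a spot was 0.0977 log2 among the Gdansk Bay samples and 0.0851 log2 among the Kiel Bight samples, a difference within that between other splits of the samples (exact permutation test, two-sided p = 0.589).

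The main comparison asked which transcripts of the gill, the organ of ion exchange with the surrounding water, differed between cod of the less saline and the more saline region. At 5 of the 42475 spots the regions differed, 4 with a lower and 1 with a higher ratio in Gdansk Bay. Spot 27003 showed the largest difference of these. Its mean log2 ratio was -2.45 ± 0.11 (SD, n = 5) in Gdansk Bay and 0.997 ± 0.50 (SD, n = 3) in Kiel Bight, a difference of -3.45 (SE 0.20, limma adjusted p = 0.0063). The Kiel Bight level was thus 10.9-fold the Gdansk Bay level, with a 95% interval from 7.93 to 15.1. Whether background limited the low Gdansk Bay values, and with them this fold, was unknown without intensities. The interval also rests on a spread taken as common to both regions. The Kiel Bight samples varied more than the Gdansk Bay samples here, so it may be too narrow. Spot 36714 had a mean of -1.05 ± 0.17 (SD, n = 5) in Gdansk Bay against 0.76 ± 0.21 (SD, n = 3) in Kiel Bight. Its difference was -1.81 (SE 0.13, limma adjusted p = 0.011), or 3.502-fold with an interval from 2.86 to 4.29.

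The single spot with a higher ratio in Gdansk Bay, spot 34058, had a mean of 0.32 ± 0.06 (SD, n = 5) there and -0.44 ± 0.03 (SD, n = 3) in Kiel Bight. The difference of 0.76 (SE 0.05, limma adjusted p = 0.0063) was 1.69-fold, with an interval from 1.57 to 1.82. The remaining called spots were 2.32-fold (interval 1.97 to 2.73, limma adjusted p = 0.033) and 1.95-fold (interval 1.69 to 2.24, limma adjusted p = 0.048) lower in Gdansk Bay. At the 1.95-fold spot the Kiel Bight samples varied more (SD 0.21) than the Gdansk Bay samples (SD 0.05), so this interval may also be too narrow. At each of the 5 spots all Gdansk Bay samples lay on one side of all Kiel Bight samples. The intervals of the 5 spots were not adjusted for picking them out of all spots by the same test, so the folds may be overstated. The genes behind these spots were not identified here. Each region had its own salinity, so region and salinity were not separable in this design.

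**Figure D1:**
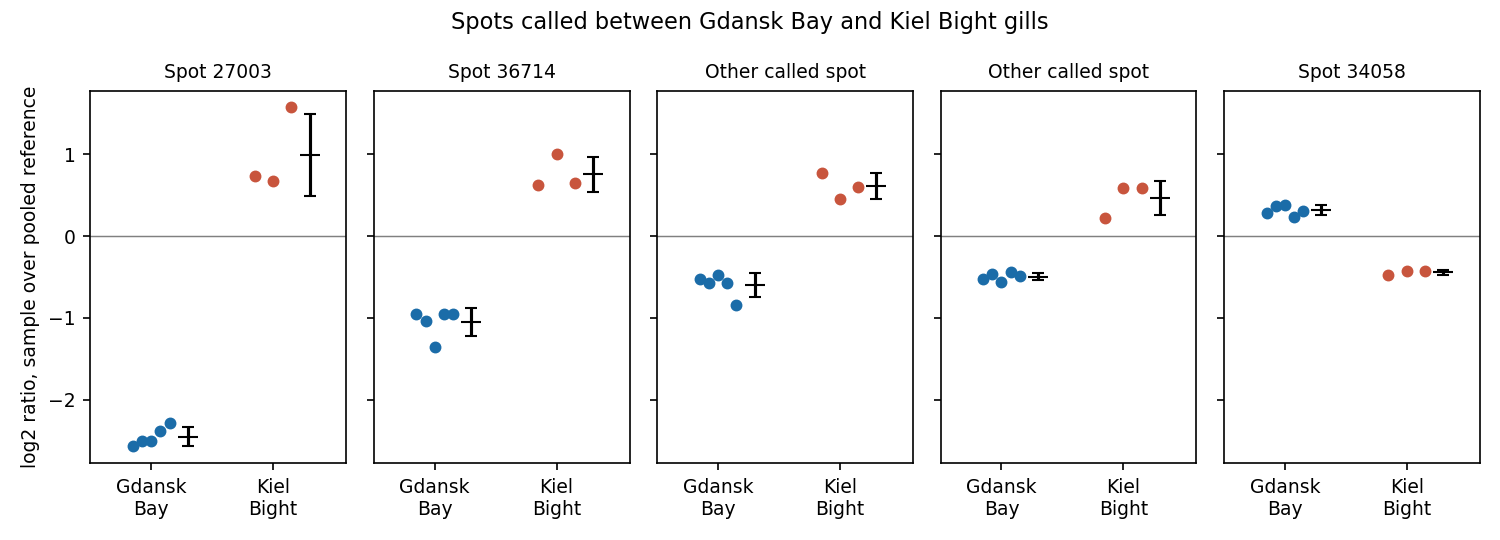
Each panel shows a spot called between the regions, with the log2 ratio of sample over pooled reference on the vertical axis, a point per sample and the mean ± SD of each region beside the points. The regions do not overlap at any of the 5 spots, and the Gdansk Bay samples of spot 27003 lie between -2.57 and -2.29 while the Kiel Bight samples lie between 0.68 and 1.58.

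The count was small and depended on single arrays. Without Gdansk Bay 1, Gdansk Bay 2, Gdansk Bay 4 or Kiel Bight 3 in turn 2 spots were called, without Gdansk Bay 3 there were 8, and without Kiel Bight 1 there were 10. With the replicate number as a block in numbers 1 to 3, 0 spots were called, against 6 in the same arrays without the block. The block adds terms to a fit of few arrays and leaves less data to estimate the spread. The differences at the named spots (-3.53, -1.87 and 0.79) were the same in both fits. The 0 thus does not separate an effect of replicate number from lost precision. An unmoderated test with unequal variances called 1 spot, spot 34058. Spot 27003 lost its call under that test, with an adjusted p of 0.666, as did spot 36714, with an adjusted p of 0.598. Spot 36714 also lost its call without Gdansk Bay 1, Gdansk Bay 2, Gdansk Bay 4 or Kiel Bight 3, with adjusted p from 0.054 to 0.086 in limma, and spot 34058 lost it without Kiel Bight 3 (limma adjusted p = 0.052). The differences themselves stayed between -3.61 and -3.16 at spot 27003, between -1.89 and -1.69 at spot 36714 and between 0.74 and 0.79 at spot 34058 over the 21 alternatives run. Over the same alternatives the adjusted p ranged from 0.000216 to 0.666 at spot 27003, from 0.00478 to 0.598 at spot 36714 and from 0.0055 to 0.351 at spot 34058. The robust, unmoderated and covariate fits, the variance filter, the minimum difference and the other threshold leave a difference unchanged by construction. The narrow ranges of the differences are thus partly fixed in advance.

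Beyond the called spots, differences between the regions did not pass the adjustment for multiple tests. An unadjusted p under 0.05 in limma was reached at 2915 spots (6.86%), of which 1272 were higher and 1643 lower in Gdansk Bay. The regions did not overlap at 2253 spots (5.30%), against 3.57% given by chance for 5 samples against 3. That share is a mean over the 56 splits, which ranged from 1.85% to 11.6%, and 8 of them gave as many spots as the regions or more. As many spots at an unadjusted p under 0.05 were given by 13 of the 56 splits, so larger counts than those of the regions were found in other groupings of these samples. Differences of at least 1 log2 were found at 284 spots, 159 higher and 125 lower in Gdansk Bay. Of these, 102 had no overlap between the regions, 55 higher and 47 lower. These were not called, apart from the 3 called spots with a difference of that size.

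A further comparison asked whether samples of a region resembled each other over the whole array. Pearson's r over spots, which are not independent replicates, averaged 0.12 ± 0.15 (SD) over the 10 pairs within Gdansk Bay, 0.17 ± 0.08 over the 3 pairs within Kiel Bight and 0.04 ± 0.13 over the 15 pairs between regions. The mean between-region distance was 0.957 and the mean within-region distance 0.868. Their difference of 0.089 was reached by 4 of the 56 splits (exact permutation test, one-sided p = 0.071), so a separation beyond the spread between samples was not shown. With Euclidean distance the exact permutation test gave p = 0.036, without Gdansk Bay 5 it gave p = 0.029 and without Kiel Bight 2 it gave p = 0.048. The last 2 values are the smallest that the exact test can give with those samples left out. With all samples the smallest possible is 0.018. Leaving out each other sample gave p from 0.086 to 0.257 in the same test. The highest correlation, 0.38, joined Gdansk Bay 2 and Gdansk Bay 5. Kiel Bight 3 correlated with Gdansk Bay 5 at 0.24, and Kiel Bight 2 with Gdansk Bay 4 at 0.26, above the 0.08 between Kiel Bight 1 and Kiel Bight 3.

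**Figure D2:**
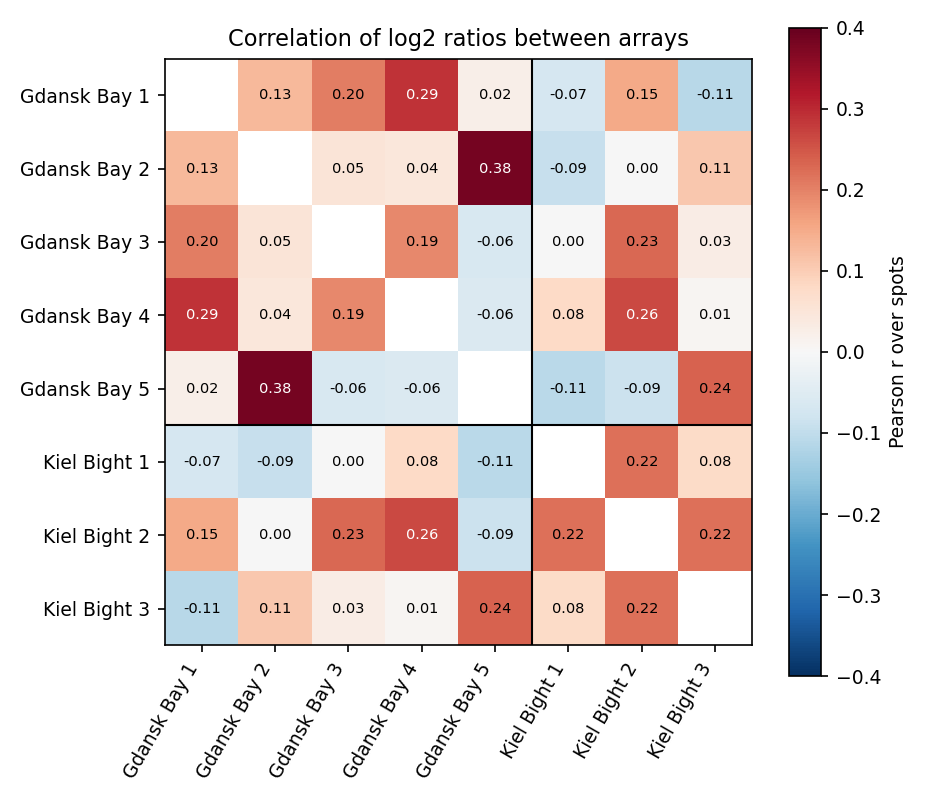
Pearson correlation of log2 ratios over 42475 spots for each pair of arrays, with lines between the regions and colour giving r from -0.4 to 0.4. Pairs between regions reach 0.26, within the range of the pairs inside a region, and the highest value is 0.38 for Gdansk Bay 2 and Gdansk Bay 5.

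Some spots differed sharply between samples. A gap of at least 2 log2 parted the samples at 176 spots (0.414%). At 82 of these a single sample lay above the others, at 35 a single sample lay below, and at 59 between 2 and 6 samples were high. The single high sample was Gdansk Bay 1 at 24 spots and Gdansk Bay 5 at 1 spot. The single low sample was Kiel Bight 1 at 11 spots and Kiel Bight 3 at 9 spots, against at most 4 in any other sample. Of the 59 spots with 2 to 6 high samples, 34 had high samples from both regions, 17 from Gdansk Bay only and 8 from Kiel Bight only. All 3 Kiel Bight samples were high and all 5 Gdansk Bay samples low at 3 spots, of which spot 27003 was called. The other 2 had mean differences of -4.17 and -4.77, larger than that of spot 27003, but the Kiel Bight samples varied widely there (SD 1.09 and 1.48) and the limma adjusted p was 0.155 and 0.187. The reverse pattern, high in all Gdansk Bay samples and low in all Kiel Bight samples, was seen at 0 spots. It needs exactly 5 high samples, which only 2 spots had, against 22 spots with 3 high samples. The 0 thus says little about a direction. With a gap of at least 3 log2, 52 spots remained and 0 parted the regions. The 3 spots above missed that limit narrowly. Spot 27003, for example, ran from 0.677 in the lowest Kiel Bight sample to -2.29 in the highest Gdansk Bay sample. A gap of at least 1.5 log2 gave 327 spots, 5 of them parting the regions.

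**Figure D3:**
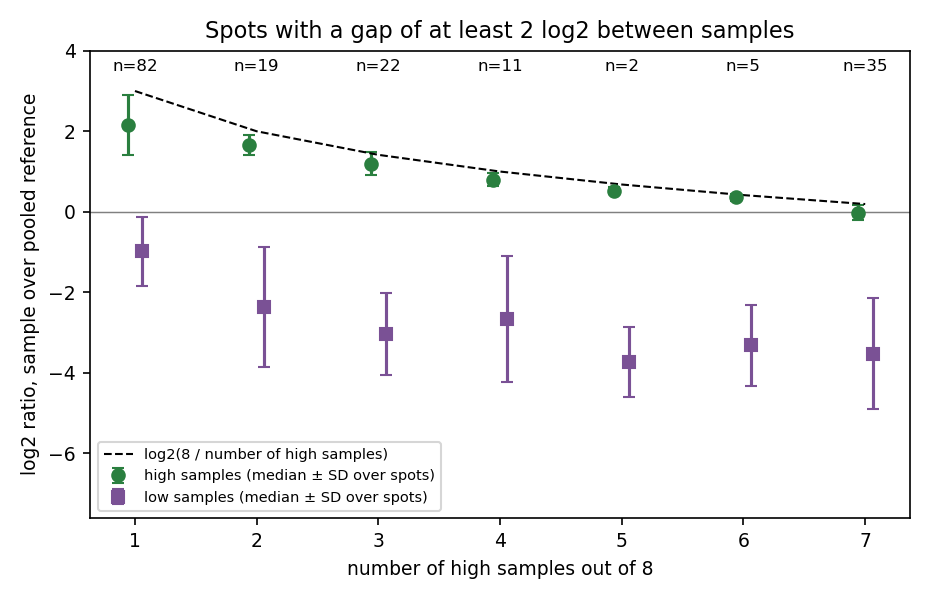
Spots with a gap of at least 2 log2 between samples, by the number of high samples out of 8 (horizontal axis), with the log2 ratio of high and low samples on the vertical axis as the median ± SD over spots, and n the number of spots. The high level falls from 2.16 with 1 high sample to -0.03 with 7, and lies below the dashed line of log2 of 8 over the number of high samples. With 1 high sample it deviates from the line by a median of -0.843. Because the reference pools the same samples, a wide gap alone brings the high level towards the line. Closeness to it thus does not show a target absent from the low samples.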

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

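Of the tests in this part, those on splits of the arrays, on position, on arrays left out of the fit and the covariate fit were chosen after the results they bear on, or earlier versions of the same tests, had been seen. Among 12 sets of 5 Gdansk Bay values tested for a sample far from the others, 2 were singled out, and chance alone would single out about 1 set in 20. At spot 36714 Gdansk Bay 3 had a log2 ratio of -1.36, while the other Gdansk Bay samples lay between -1.04 and -0.95. At the called spot with a 2.32-fold difference Gdansk Bay 5 had -0.847, while the others lay between -0.579 and -0.477. In each case the far sample lay farther from Kiel Bight than the others did. Over all spots 5.77% had such a sample.

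The call of 5 spots between regions was set against all 56 splits of the arrays into 5 and 3. In 3 of the 56 splits, the real one included, at least 5 spots were called, so chance is not excluded. The highest other split called 763 spots and the next 7, and 43 splits called 0. For the 2915 spots at an unadjusted p under 0.05, 13 of the 56 splits, in permutation of the labels, gave as many, and the highest gave 6920. For the 2253 spots without overlap between the regions 8 of the 56 splits gave as many, and the highest gave 4931, so chance is not excluded for these counts either. With the first within-region component as a covariate 4 spots were called, all among the 5. That component was taken from deviations within regions, so by construction it cannot change a difference between regions. It only alters the spread, and 3880 spots then had an unadjusted p under 0.05 in limma. The fit therefore does not test whether a hidden structure lies behind the calls.

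The split with 763 called spots set Gdansk Bay 2, Gdansk Bay 5 and Kiel Bight 3 against the rest, which points to a structure of the samples other than the regions. Of its spots 407 were higher and 356 lower in these 3 arrays, with a median difference of 0.529 log2 in size, and 0 were among the 5 called between regions. Position on the array is argued against: the spots 1 or 85 numbers away from the called ones moved with them by a median of only 0.0077 log2 (95% bootstrap interval 0.0013 to 0.0155). The spacing of 85 was inferred from the data, as the one at which log2 ratios correlated most among those tried (mean r 0.038), and this test replaced a first version over all spots, which gave a correlation of 0.016 between differences 85 numbers apart but diluted the called spots. Without an array the split called 1 spot (Gdansk Bay 5), 5 (Gdansk Bay 1), 12 (Gdansk Bay 4), 29 (Kiel Bight 2), 54 (Gdansk Bay 2), 567 (Kiel Bight 3), 895 (Gdansk Bay 3) or 1469 (Kiel Bight 1), so its count depended on single arrays. To ask whether 1 array alone carried it, each array was placed, at the spots called without it, on a scale from 0 (mean of the rest) to 1 (mean of the 3 arrays, or of those left). This replaced a count of spots for an array against the other 7, at most 179, which is not comparable with a split into 5 and 3. Kiel Bight 3 lay at a median of 0.578 (95% bootstrap interval 0.545 to 0.614) and Gdansk Bay 2 at 0.640 (0.532 to 0.706), nearer to the 3. Gdansk Bay 5 had only 1 spot to be placed by, at 0.041. The intervals take spots as independent and are too narrow. The split itself had been picked with all arrays included, as the one that called most spots. These positions partly restate that choice, so they do not decide whether 1 array alone carried it.

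Whether the 3 arrays shared a slide with another of the arrays stays open. Among the 35 splits into 4 and 4, the one that added Kiel Bight 1 to the 3 arrays called 327 spots and the next 5. Over all spots Kiel Bight 1 correlated with Gdansk Bay 2 at -0.091, with Gdansk Bay 5 at -0.109, with Kiel Bight 3 at 0.077 and on the other side with Gdansk Bay 1 at -0.066, with Gdansk Bay 3 at -0.003, with Gdansk Bay 4 at 0.081 and with Kiel Bight 2 at 0.220, so the correlations do not place it clearly on either side. On the scale from 0 (the rest) to 1 (the 3 arrays) Kiel Bight 1 lay at 0.285 (0.237 to 0.347) and Gdansk Bay 3 at 0.327 (0.301 to 0.347), between the sides but nearer to the rest, Kiel Bight 2 lay at -0.081 (-0.233 to 0.108), and Gdansk Bay 1 and Gdansk Bay 4 had only 5 and 12 spots. A slide shared with arrays not analysed here, other batches of handling, and differences in the cell make-up, sex or condition of the fish stay open too and were not tested.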

How the results depend on the processing

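The 5 called spots became 4 with median-centred, quantile-normalized or scaled arrays, with a robust prior and with the replicate number as a random block, and stayed 5 with array weights and at an adjusted p under 0.1; in each of these the calls were all among the original 5. The higher-variance spots alone gave 8, which held the 5. The unmoderated test with unequal variances gave 1, and requiring a difference of at least 1 log2 gave 3. Leaving out each array gave 2 to 10, and the spots called changed too. Among the original 5 were 1 of 2 without Kiel Bight 3, 3 of 8 without Gdansk Bay 3 and 4 of 10 without Kiel Bight 1. The same held for 4 of 6 without Gdansk Bay 5, 3 of 4 without Kiel Bight 2 and both of 2 without Gdansk Bay 1, 2 or 4. Of the 3 named spots none changed direction. Leaving out arrays could not reverse them, as they had been picked for no overlap between the regions. With the replicate number as a block in numbers 1 to 3, which leaves out Gdansk Bay 4 and 5, 0 spots were called in limma, with 2406 at an unadjusted p under 0.05, while the same 6 arrays without the block, a fit added later, gave 6, of which 1, spot 34058, was among the 5. Spots 27003 and 36714 lost their calls in both of these fits, and spot 34058 lost its call with the block and, by construction, where a difference of at least 1 log2 was required. The block leaves less data to estimate the spread, so its 0 calls can reflect lost precision. Deviations of same-numbered samples correlated at 0.03, -0.13 and -0.10, which gave no sign of pairing. They were not set against samples of unlike number, so a shared slide or batch is not excluded. The between-region minus within-region distance of 0.089 was 0.043 with Spearman (exact permutation test, p = 0.25) and 0.090 on higher-variance spots (p = 0.071 in the same test). Neither p passed 0.05. The test passed with Euclidean distance, where the difference was 4.82 on its own scale. Leaving out each array gave a difference of 0.046 to 0.115 with Pearson's r. Causes were not tested. Background correction, probe averaging and gene-level settings could not be varied on this table, and without intensities it is unknown how signal over background limits each spot.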

Other observations

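All tests in this part, with the limit of -0.2 log2, were chosen after the data or related values had been examined. The reference was labelled as a mix of all samples, which can be checked spot by spot. In the 425 most variable spots the mean log2 ratio over the 8 samples had a median of -0.473, while the mean of the ratios on the linear scale had a median of 1.01 (interquartile range 0.935 to 1.11). A mean log2 ratio below 0 at a variable spot is thus what an evenly mixed pool gives.

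At the wide-gap spots with 2 to 6 high samples, a target carried by the high samples alone and a target only lower in the others cannot be told apart. If k of 8 equally mixed samples alone carry a target, each should lie at log2(8/k), and over the 59 spots the median deviation from this level was -0.217 log2 (95% bootstrap interval -0.327 to -0.146). A target present in all samples, but lower in some, would from the pool alone give a median deviation of -0.124 at the measured levels and -0.503 at the smallest gap allowed. The measured deviation lies between these values, so it does not show that the target was absent from the low samples. The 82 spots with 1 high sample deviated by a median of -0.843.

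A defect of single spots would leave the other 7 samples at 0. At the 82 spots with 1 high sample they lay at a median of -0.985 (interval -1.19 to -0.826), which argues against a defect as the whole cause, although 6 of the 82 lay above -0.2. At the 35 spots with 1 low sample the other 7 lay at -0.026 (interval -0.089 to 0.0091), below the 0.193 of a target missing from 1 sample, which is consistent with a defect. The mean linear ratio there had a median of 0.922, against 1.01 to 1.05 at the spots with fewer high samples. The deviation from the level of a missing target was -0.219 here and -0.217 at spots with 3 high samples. The nearest classes, with 6 and 5 high samples, deviated less (-0.056 and -0.151) but held only 5 and 2 spots, so this test is weak. Of the 35 low values 11 were on Kiel Bight 1 and 9 on Kiel Bight 3.

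The 3 wide-gap spots that parted the regions exactly, all high in Kiel Bight, were set against the 56 splits of the arrays. In 2 of the 56 splits, the real one included, at least 3 such spots were parted. That share lies under 0.05, but the highest other split also parted 3. With a gap of at least 3 log2, 0 spots parted the regions. The lowest Kiel Bight and highest Gdansk Bay values of the 3 spots were 0.158 and -2.72, 0.677 and -2.29, and -0.655 and -3.61. All 3 thus missed that limit narrowly, so the 0 says little about them. The count of 3 is part of a family of 5 computed over the same splits. The 8 spots high in Kiel Bight samples only were matched by 3 of the 56 splits, the 17 high in Gdansk Bay samples only by 7, and the 3 high in all Kiel Bight samples and no other by 2. High in all Gdansk Bay samples and no other were 0 spots, where the mean over the splits was only 0.036, so that 0 gives no direction. The count was not adjusted for this family or for the choice of gap, so it does not exclude chance, splits were not run for other gaps, and spots of the same gene may be counted more than once.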
